A study of Drosophila melanogaster with 8 samples.

How the data were processed

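RNA sequencing libraries from adult Drosophila melanogaster ovaries, dissected on days 1 to 3 after eclosion, were compared in 8 libraries: for each of the germline drivers nosGAL4 and bamGAL4, 2 control libraries and 2 libraries labelled as a germline knockdown of stwl (stonewall). Total RNA was extracted from dissected ovaries with Trizol and made into libraries with a directional kit, per the labels' protocols. The control flies of the nosGAL4 pair carried the chromosome 3 balancers MKRS and TM6 and the knockdown flies carried the hairpin over TM6, while the bamGAL4 control carried no balancer in its listed genotype, per the labels.

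The values used are estimated counts per gene as deposited by the authors, with 1 column per library and no scaling between libraries. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.6, STAR 2.7.5b and Salmon 1.2.1 with the genome build dm6, without the order or role of the tools. Between 92.51% and 95.05% of the values of a library were whole numbers and the rest had up to 3 decimals. The gene annotation, the strand setting of the counting and any filter on genes are not given in the sources used here, so overlapping and antisense genes may share reads, and so may near-identical gene copies. Each table listed 14094 genes, of which 14048 identifiers were found in the reference annotation used for symbols and positions (BDGP6.54, whose coordinates are those of dm6). Total counts ran from 7473851 to 12174984 per library. A count of 3, used as the detection floor, came to between 0.238 and 0.405 on the scale of normalised CPM, depending on the library. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

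Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 8957 genes. With edgeR 4.0.16 (limma 3.58.1, R 4.3.3), TMM factors were computed and 1 quasi-likelihood model with the 4 groups as levels was fitted robustly to all 8 libraries, leaving 4 residual degrees of freedom. The contrasts were knockdown against control with nosGAL4, the same with bamGAL4, and the nosGAL4 effect minus the bamGAL4 effect, which tests whether the drivers differ. P-values were adjusted by Benjamini-Hochberg over all genes tested in a contrast, with a threshold of 0.05. CPM values are scaled by the TMM factors. Log2 fold changes are given with their standard error (SE), obtained from the F statistic, and a prior count of 0.125. Where every library of a group had a count of 0, the fold is a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio of summed counts is given with its 95% counting interval.

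There were 28 gene lists, written before the data were examined, as were the model, the contrasts, the thresholds, the rule for naming genes and all alternatives except the correction for transcript length and the marking of overlapping genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a contrast. Counts of list members are given over all genes tested and adjusted over the list alone. The naming rule took stwl, nos and bam, the 8 largest rises and the 8 largest falls per driver among genes that passed the test, had no overlap between groups and reached a mean of at least 5 CPM, with 2 further genes per direction that carry placeholder symbols. It also took from each list up to 4 members that passed the test, by smallest adjusted p, or the 2 with the smallest p where none passed. For the difference between drivers it took the 5 largest per direction. Any other gene named is said to have been chosen after its values were seen.

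The model was tested on simulated counts drawn from the libraries' means and sizes, with 200 genes changed by known folds. For the nosGAL4 contrast, over 7823 genes, 15.91% of the genes changed 2-fold were recovered, 70.45% of those changed 4-fold, 89.36% of those changed 8-fold and 95.56% of those changed 16-fold. In that contrast 13 of the 136 genes called had not been changed. For the difference between drivers the recovered shares were 2.273%, 50%, 72.34% and 86.67%, and 7 of 103 calls were of unchanged genes. In the unchanged bamGAL4 contrast 6 genes were called. Of the 28 lists, the 1 shifted list was called and 0 of the other 27. Simulated genes were drawn independently, and these lists were sets of random genes. In the real data the estimated correlation within a list reached 0.716, and 59.2% (nosGAL4) and 68.1% (bamGAL4) of the genes were called. The simulation therefore does not show the error rates at such correlations or with so many genes changed.

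The alternatives were RLE size factors, library totals with no further scaling, scaling to the cytoplasmic ribosomal protein genes alone, DESeq2 1.42.0, no filter on low counts, a stricter filter (at least 5 CPM in at least 2 libraries), each driver's own 4 libraries, a replicate block, genes outside chromosome 3, leaving out eggshell and yolk genes, a minimum fold change of 2, and leaving out each library in turn. An offset per library from a smooth trend on transcript length was added after a trend on length was seen in the difference between drivers. That offset takes out any change that follows length, including a change that comes from the knockdown. Random lists matched on length or on expression were drawn 10000 times from the 40 nearest genes. Figures were drawn with matplotlib 3.10.9. Whether the 2 libraries of a group came from separate crosses or from 1 pool of flies is not given in the sources used here, so p-values measure the spread between these samples. Reads from the hairpin cannot be separated from those of the gene in counts per gene, and no read files were available.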

Results

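Messenger RNA was measured in adult ovaries of Drosophila melanogaster in which stwl, the gene for the chromatin-associated MADF-domain protein Stonewall, was targeted by RNA interference in the germline. The drivers were nosGAL4, active in germline stem cells and later germ cells, and bamGAL4, active in dividing germline cysts. Each driver had 2 control libraries and 2 libraries labelled knockdown, so that 4 groups of 2 libraries were compared. Total counts were 8449048 and 10389313 in the nosGAL4 controls and 8459977 and 8531273 in the nosGAL4 libraries labelled knockdown. They were 7473851 and 11503624 in the bamGAL4 controls and 12174984 and 11133866 in the bamGAL4 libraries labelled knockdown. Between 8396 and 10445 genes had a count in a library. Across genes, the Pearson correlation of log2 CPM between the 2 libraries of a group was 0.98 for the nosGAL4 controls, 0.925 for the nosGAL4 libraries labelled knockdown, 0.97 for the bamGAL4 controls and 0.984 for the bamGAL4 libraries labelled knockdown. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom from 12.45 to 135.2. The study's title names genome organization, nuclear pore complex formation and differentiation in oogenesis, and the comparisons ask which genes stwl keeps high or low in the ovary when it is targeted with either driver.

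No fall of the targeted gene was detected in either set of libraries labelled knockdown. With nosGAL4, stwl (FBgn0003459, dm6 3L:14402930-14409939) stood at 23.1 and 16.9 CPM in the controls and at 61.1 and 27.7 CPM in the libraries labelled knockdown. Its log2 fold change was 1.15 (SE 0.37, n = 2 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0203). The call was lost without control replicate 2 (0.93, adjusted p = 0.14) and without knockdown replicate 1 (0.46, adjusted p = 0.196). It was also lost with library totals (0.72, adjusted p = 0.115), with ribosomal protein scaling (0.50, adjusted p = 0.252), in the driver's own 4 libraries (1.07, adjusted p = 0.0776) and with a transcript length correction chosen after a trend on length was seen (0.82, adjusted p = 0.0677). With bamGAL4 it stood at 18.2 and 21.0 CPM in the controls and at 23.2 and 29.6 CPM in the libraries labelled knockdown. That log2 fold change was 0.43 (SE 0.36, adjusted p = 0.313), or 1.30 (adjusted p = 0.00886) with ribosomal protein scaling and −0.32 (adjusted p = 0.438) with the length correction. The counts therefore do not check the knockdown label, and counts per gene do not separate reads of the gene from reads of the hairpin. Germline genes did separate the labels. The mRNA of nos (FBgn0002962, 3R:19157238-19160202), which encodes the translational repressor Nanos needed to keep germline stem cells, was at 408 and 452 CPM in the nosGAL4 controls and at 4.59 and 1.46 CPM in the libraries labelled knockdown, a log2 change of −7.15 (SE 0.47). The corresponding change with bamGAL4 was −7.82 (SE 0.48). The cyst differentiation factor bam (FBgn0000158, 3R:25243039-25245109) went from 39.9 and 43.6 CPM to 0 and 0.928 CPM with nosGAL4 (−6.44, SE 0.76) and from 46.8 and 41.9 CPM to 0.0886 and 0.696 CPM with bamGAL4 (−6.82, SE 0.75). Leaving out knockdown replicate 1 gave −5.48 for bam with nosGAL4, and leaving out knockdown replicate 2 left 1 library at 0 counts. The germline helicase gene vas, chosen after its values were seen, was at 397 and 434 CPM in the nosGAL4 controls and 139 and 46.4 CPM in the libraries labelled knockdown, and at 371 and 378 against 7.89 and 21.8 CPM with bamGAL4.

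**Figure D1:**
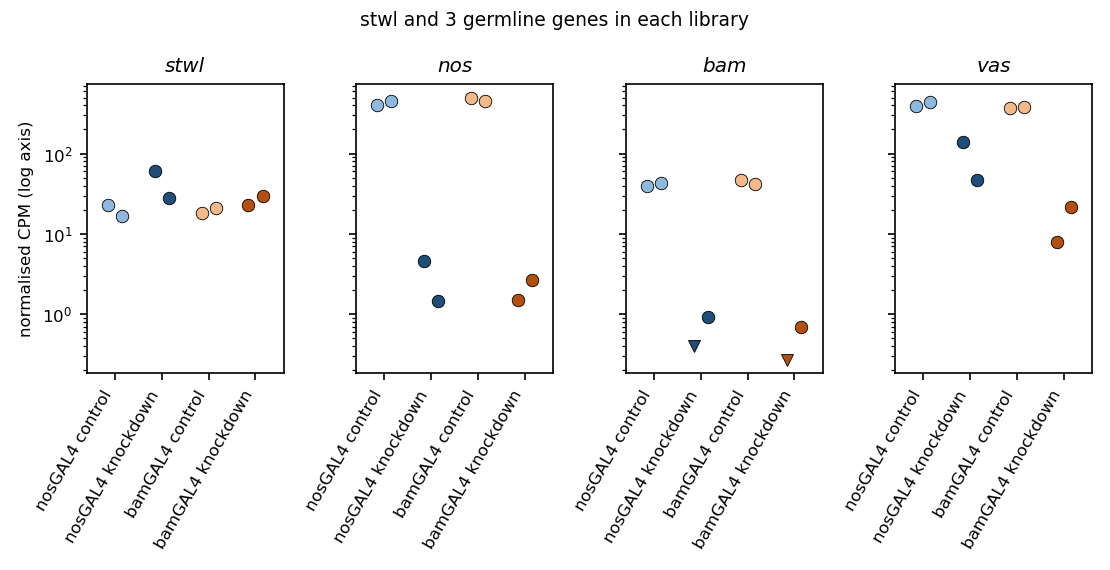
Normalised CPM (log axis) of stwl, nos, bam and vas in each of the 8 libraries, 1 point per library; a triangle marks a value below 3 counts, drawn at that floor. Points for stwl in the libraries labelled knockdown lie above those of their driver's controls, from 23.2 to 61.1 CPM, while nos, bam and vas lie below all controls.

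With nosGAL4, germline and egg genes were lower and muscle, haemocyte, neuronal and niche, escort and early follicle cell markers were higher in the libraries labelled knockdown. Among the germline markers 14 of 20 tested fell and 1 rose (14 and 1 adjusted over the list alone). Counts given as "both ways" were equal over all genes tested and adjusted over the list alone. Examples were otu (−4.76 on the log2 scale, SE 0.33) and ovo (−3.29, SE 0.39), both needed for female germline differentiation, whereas tud, a germ plasm component, rose by 3.46 (SE 0.34). The germline list had a median of −1.86 (camera adjusted p = 0.00029; adjusted p = 0.414 with an estimated correlation). Maternal mRNA and axis genes followed, with 22 of 33 lower and 4 higher both ways. Their median was −1.74 (camera adjusted p = 2.67e-05; adjusted p = 0.31 with an estimated correlation). The bicoid anchoring factor exu changed by −5.62 (SE 0.25), the primordial germ cell repressor pgc by −6.25 (SE 0.33) and the poly(A) polymerase wisp by −4.55 (SE 0.31). Without knockdown replicate 1 that list's median was −3.11. Of the meiosis genes 20 of 29 fell and 2 rose both ways. The median came to −1.39 (camera adjusted p = 8.26e-05; adjusted p = 0.413 with an estimated correlation). They included the Polo regulator mtrm (−5.71, SE 0.29) and the meiotic APC activator cort (−3.68, SE 0.34). In the piRNA pathway 17 of 34 fell and 3 rose both ways. This list had a median of −1.03 (camera adjusted p = 0.00379; adjusted p = 0.483 with an estimated correlation; median −1.70 without knockdown replicate 1). The list was at −1.63 with ribosomal protein scaling. Its largest named falls were rhi (−4.19, SE 0.36), a heterochromatin protein of piRNA clusters, and AGO3 (−3.19, SE 0.46). Vitelline membrane and chorion genes, made by follicle cells around late egg chambers, had the lowest median, −4.40, with 15 of 23 lower and 1 higher both ways (camera adjusted p = 1.79e-06; adjusted p = 0.413 with an estimated correlation). That median was −7.02 without knockdown replicate 1, and Femcoat (−8.33, SE 0.36) and Cp16 (−7.42, SE 0.60) were examples. Cell cycle and DNA replication genes fell in 26 of 34 cases with 0 rises both ways. The median of the list was −1.99 (camera adjusted p = 2.67e-08; adjusted p = 0.413 with an estimated correlation). They included the cyclin CycB3 (−3.85, SE 0.25) and the mitotic kinase polo (−2.68, SE 0.23).

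Most nucleoporins were also lower with nosGAL4, while lists of nuclear transport and chromatin genes had medians below 0 with members on both sides. Of the nucleoporins 20 of 30 fell and 0 rose (21 fell adjusted over the list alone). The list's median stood at −1.08 (camera adjusted p = 1.38e-05; adjusted p = 0.413 with an estimated correlation). Aladin changed by −2.31 (SE 0.26), Nup58 by −2.09 (SE 0.25), Gle1 by −2.11 (SE 0.26) and Nup43 by −2.12 (SE 0.27). Nuclear transport receptors and Ran genes had a median of −0.50, with 7 of 20 lower and 1 higher, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0271; adjusted p = 0.483 with an estimated correlation). The Ran exchange factor Rcc1 (−3.05, SE 0.30) and the importin Pen (−3.44, SE 0.35) were the most significant. Genes of the nuclear lamina and inner nuclear membrane moved in both directions (median −0.42, 4 of 10 lower and 2 higher both ways, camera adjusted p = 0.347). The inner membrane protein gene MAN1 changed by −1.25 (SE 0.21) and the nuclear anchor Msp300, which muscle also uses, by 7.50 (SE 0.45). The H3K9 methylation and heterochromatin list had a median of −0.61 (9 of 22 lower and 3 higher, 8 and 3 adjusted over the list alone, camera adjusted p = 0.0127; adjusted p = 0.413 with an estimated correlation). The heterochromatin protein gene Su(var)3-7 changed by −1.91 (SE 0.24). The Polycomb group had a median of −0.94 (13 of 20 lower and 4 higher, 14 and 4 adjusted over the list alone, camera adjusted p = 0.0163; adjusted p = 0.34 with an estimated correlation). Its members split, since esc (−2.34, SE 0.30) fell while Su(z)2 (3.21, SE 0.32) and ph-p (2.68, SE 0.31) rose. Insulator and architectural proteins had a median of −0.60 (11 of 21 lower and 1 higher both ways, camera adjusted p = 0.0127; adjusted p = 0.413 with an estimated correlation). The repressor gene insv changed by −2.76 (SE 0.27). Germline stem cell and cyst differentiation factors had a median of −0.89 (13 of 21 lower and 5 higher both ways, camera adjusted p = 0.0202; adjusted p = 0.483 with an estimated correlation). MADF domain proteins were not called as a list (median −0.54, 3 of 9 lower and 2 higher both ways, camera adjusted p = 0.247). With library totals and with ribosomal protein scaling the medians were −0.92 and −1.07 for the transport list, −1.01 and −1.16 for H3K9, −1.01 and −1.19 for insulators, −0.83 and −0.997 for the lamina and −0.96 and −1.11 for MADF proteins. Ribosomal protein scaling gave −1.62 for nucleoporins, −1.52 for Polycomb and −1.46 for stem cell and cyst factors. The length correction gave −1.43 for nucleoporins (26 lower, 0 higher) and −0.90 for H3K9 (17 of 22 lower, 1 higher). It gave −1.34 for Polycomb (16 lower, 2 higher) and −0.98 for insulators (14 lower, 1 higher). The transport list was then at −0.75 (10 of 19 lower, 1 higher) and the lamina list at −0.77 (5 lower, 2 higher). These values stood beside a rise of the markers of muscle, haemocytes and fat body in the same libraries.

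Lists of muscle, haemocyte and fat body, neuronal, niche and follicle cell markers were called as higher with nosGAL4. All 21 muscle sheath markers tested rose. Their median was 6.23 (camera adjusted p = 3.71e-11; adjusted p = 0.31 with an estimated correlation; 21 adjusted over the list alone). The titin-like sls changed by 9.11 (SE 0.44) and the troponin gene TpnC73F by 7.12 (SE 0.28). Of the haemocyte and fat body markers 22 of 24 rose and 0 fell (23 adjusted over the list alone). The median came to 6.02, or 5.52 with 6 members set at their bound (camera adjusted p = 1.81e-07; adjusted p = 0.31 with an estimated correlation). The phagocytosis receptors eater (3R:27095867-27099679) and NimC1 (2L:13973158-13976769) were at least 1022-fold and at least 687-fold higher, against control libraries with 0 counts, and the haemocyte gene Hml changed by 10.06 (SE 0.47). Neuronal genes rose in 14 of 16 cases with 0 falls both ways. This list had a median of 5.76, or 5.50 with 3 members at their bound (camera adjusted p = 3.98e-05; adjusted p = 0.31 with an estimated correlation). The complexin gene cpx changed by 7.70 (SE 0.52) and elav by 4.41 (SE 0.35). Niche, escort and early follicle cell markers rose in 20 of 27 cases and fell in 3 (21 and 3 adjusted over the list alone). The median of the list was 3.84, or 3.76 with 3 at their bound (camera adjusted p = 4.54e-05; adjusted p = 0.226 with an estimated correlation). The Hedgehog effector ci changed by 5.10 (SE 0.29), the adhesion protein Fas3 by 5.42 (SE 0.31) and the escort cell ligand Wnt4 by 6.40 (SE 0.42). Follicle cell and border cell markers had a smaller median of 1.89 (13 of 18 higher and 1 lower both ways, camera adjusted p = 0.00235; adjusted p = 0.31 with an estimated correlation). The adhesion gene Fas2 changed by 5.34 (SE 0.28). BMP signalling genes had a median of 1.49 (13 of 20 higher and 1 lower both ways, camera adjusted p = 0.0089; adjusted p = 0.34 with an estimated correlation). With ribosomal protein scaling that median was 0.94. The ligand gene dpp changed by 5.78 (SE 0.37) and the feedback inhibitor Dad by 3.84 (SE 0.35). Oviduct, spermatheca and gut markers rose in 8 of 12 cases with 0 falls both ways. The list's median stood at 7.14, or 5.24 with 7 members at their bound (camera adjusted p = 0.0163; adjusted p = 0.414 with an estimated correlation). In the ovary controls of both drivers, 16 of the 21 muscle markers, 9 of the 24 haemocyte and fat body markers, 2 of the 16 neuronal genes and 0 of the 12 oviduct, spermatheca and gut markers reached a mean of 5 CPM. The last 2 lists had 28 and 18 members before the expression filter. Members near 0 in the controls could pass it only through libraries where they were higher. The counts of rises and falls, the medians and the list tests of these 2 lists, with either driver, were therefore partly set by the filter.

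Heat shock and ribosomal protein lists were also called with nosGAL4. Of the heat shock protein genes 13 of 18 rose and 2 fell both ways. Their median was 3.06 (camera adjusted p = 0.0212; adjusted p = 0.491 with an estimated correlation). The co-chaperone gene stv changed by 6.06 (SE 0.41) and Hsp23 by 3.28 (SE 0.35). This call was lost without knockdown replicate 1 (median 3.05, adjusted p = 0.0584) or knockdown replicate 2 (2.78, adjusted p = 0.0703). Ribosomal protein genes had a median of 0.62 (36 of 79 higher and 0 lower, 22 and 0 adjusted over the list alone, camera adjusted p = 0.00214; adjusted p = 0.656 with an estimated correlation). RpL22 changed by 1.78 (SE 0.22). That call was lost without knockdown replicate 1 (median 0.32, adjusted p = 0.0637), and with library totals alone (0.21, adjusted p = 0.0607) or scaling to these genes themselves (0.04, adjusted p = 0.213). The length correction left a median of 0.40, with 27 of 79 higher. Apoptosis, DNA damage and stress signalling genes moved in both directions (median 1.13, 16 of 28 higher and 10 lower both ways, camera adjusted p = 0.252). In that list the stress transcription factor Xrp1 changed by 5.00 (SE 0.27) and the translation inhibitor Thor by 4.36 (SE 0.28). The ecdysone list (median 1.59, 12 of 22 higher and 4 lower both ways, camera adjusted p = 0.0957), the yolk protein and uptake list (0.25, 2 of 9 higher and 1 lower both ways, camera adjusted p = 0.789) and the testis-enriched list (0.78, 2 of 8 higher and 2 lower both ways, camera adjusted p = 0.931) were not called. Early oogenesis genes were not called either (median 0.42, mean 1.99, 7 of 14 higher and 5 lower both ways, camera adjusted p = 0.736). Among them RpL22-like, a ribosomal protein paralog, was at least 592-fold higher and the double-stranded RNA binding protein gene blanks changed by 6.05 (SE 0.64, or 5.06 without knockdown replicate 1).

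Across the 8957 genes tested, 3004 were higher and 2303 lower with nosGAL4 in the libraries labelled knockdown (59.2% of the genes), of which 2625 and 1728 changed at least 2-fold. With library totals alone the numbers were 2449 higher and 3246 lower, and with scaling to ribosomal protein genes 2186 and 3284, so the balance of rises and falls depended on the scaling. The groups did not overlap for 79.8% of genes, where chance gives 33.3% for 2 against 2. Among the largest rises were the extracellular matrix gene dpy (at least 874-fold), the neuropeptide-like gene Nplp3 (at least 695-fold), Ance-5 (at least 688-fold), the nicotinic receptor subunit nAChRbeta3 (at least 390-fold), the potassium channel gene slo (at least 283-fold), CG9411 (at least 1094-fold) and CG15695 (at least 400.1-fold). The largest falls included kappaB-Ras (at least 75.7-fold lower), mei-217 (at least 42.8-fold), the protease gene snk (at least 37.2-fold), CG18088 (at least 163-fold), CG12716 (at least 160-fold) and plu, with a ratio of 347 (95% counting interval 95.7 to 2867). Pstk was at least 53-fold lower, but its call was lost without control replicate 1 (adjusted p = 0.0551), knockdown replicate 1 (adjusted p = 0.0561) or knockdown replicate 2 (adjusted p = 0.06). Values of kappaB-Ras, mei-217 and Pstk are uncertain, since each overlaps another gene on its own strand.

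With bamGAL4, germline and egg genes were again lower in the libraries labelled knockdown. Vitelline membrane and chorion genes fell in 22 of 23 cases and rose in 1 both ways. The median came to −9.34 (camera adjusted p = 3.66e-08; adjusted p = 0.485 with an estimated correlation). The eggshell gene yellow-g2 was at least 3749-fold lower, Cp36 changed by −10.14 (SE 0.49), Cp15 by −11.66 (SE 1.39), Cp7Fc by −10.44 (SE 1.37) and Cp19 by −10.40 (SE 1.57). The count ratios of Femcoat and Vm26Ac were 5250 (942 to 207400) and 3243 (582 to 128140). Germline markers had a median of −3.41 (16 of 20 lower and 1 higher both ways, camera adjusted p = 9.94e-05; adjusted p = 0.524 with an estimated correlation). Examples were otu at −6.72 (SE 0.37), mael at −2.51 (SE 0.26) and tud at 3.84 (SE 0.35). Maternal mRNA and axis genes had a median of −3.25 (22 of 33 lower and 4 higher both ways, camera adjusted p = 0.000185; adjusted p = 0.333 with an estimated correlation). In that list exu changed by −7.22 (SE 0.26), pgc by −8.04 (SE 0.37) and wisp by −6.00 (SE 0.34). The anterior determinant bcd had a count ratio of 1716 (308 to 67816). Meiosis genes had a median of −1.997 (21 of 29 lower and 1 higher both ways, camera adjusted p = 5.08e-05; adjusted p = 0.485 with an estimated correlation). There mtrm changed by −9.82 (SE 0.38) and cort by −5.73 (SE 0.38). In the piRNA pathway the median was −2.26 (19 of 34 lower and 6 higher, 20 and 6 adjusted over the list alone, camera adjusted p = 0.00518; adjusted p = 0.525 with an estimated correlation). Named falls were rhi at −4.96 (SE 0.38) and vret at −3.19 (SE 0.31). Cell cycle and DNA replication genes fell in 30 of 34 cases with 0 rises both ways (median −2.85, camera adjusted p = 5.15e-08; adjusted p = 0.485 with an estimated correlation). Examples included twe (−4.53, SE 0.37) and the replicative helicase subunit gene Mcm3 (−3.49, SE 0.30). Germline stem cell and cyst differentiation factors had a median of −1.41 (13 of 21 lower and 3 higher both ways, camera adjusted p = 0.0283; adjusted p = 0.525 with an estimated correlation). That call was lost without bamGAL4 knockdown replicate 1 (−1.35, adjusted p = 0.0545) and without nosGAL4 knockdown replicate 1 (−1.33, adjusted p = 0.0534).

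Of the nucleoporins 21 of 30 fell and 3 rose with bamGAL4 (22 and 3 adjusted over the list alone). This list had a median of −1.35 (camera adjusted p = 0.000204; adjusted p = 0.525 with an estimated correlation). After the length correction the median was −1.91, with 29 lower and 0 higher. Nup43 changed by −2.66 (SE 0.26), Nup58 by −2.46 (SE 0.25), Gle1 by −2.52 (SE 0.26) and Aladin by −2.49 (SE 0.26), while the nuclear basket gene Mtor, chosen after its value was seen, changed by 1.14 (SE 0.31). Nuclear transport receptors and Ran genes (median −0.32, 7 of 20 lower and 1 higher both ways, camera adjusted p = 0.0886) were not called, but Rcc1 changed by −4.05 (SE 0.32), Pen by −3.27 (SE 0.35) and Ran by −1.98 (SE 0.26). The lamina list (median −0.16, 4 of 10 lower and 3 higher both ways, camera adjusted p = 0.542) and the H3K9 list (−0.47, 10 of 22 lower and 3 higher, 9 and 3 adjusted over the list alone, camera adjusted p = 0.0812) were not called. The same held for the Polycomb list (−0.64, 9 of 20 lower and 4 higher, 10 and 5 adjusted over the list alone, camera adjusted p = 0.333), the insulator list (−0.68, 10 of 21 lower and 2 higher, 9 and 2 adjusted over the list alone, camera adjusted p = 0.0812) and the MADF list (−0.83, 6 of 9 lower and 0 higher both ways, camera adjusted p = 0.154). With scaling to ribosomal protein genes the medians of these lists, the nucleoporins apart, lay above 0, and with RLE size factors the lamina median was 0.07. The length correction moved them the other way. The medians were then −0.95 for transport (13 of 19 lower, 1 higher) and −1.19 for H3K9 (17 of 22 lower, 1 higher). They were −1.26 for Polycomb (14 of 20 lower, 2 higher) and −1.03 for insulators (13 of 21 lower, 1 higher). The lamina and MADF medians were −0.90 and −0.85. Without control replicate 1 the transport list (−0.57, adjusted p = 0.0389) and the H3K9 list (−0.70, adjusted p = 0.0328) passed. Within these lists the lamina-associated baf changed by −1.75 (SE 0.23), the HP1 family gene HP1c by −1.81 (SE 0.25), Su(z)2 by 4.30 (SE 0.34), ph-p by 4.01 (SE 0.32) and BEAF-32 by −2.05 (SE 0.24). Muscle, haemocyte and fat body markers rose in the same libraries.

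All 21 muscle sheath markers rose with bamGAL4 (21 adjusted over the list alone). The median of the list was 6.21 (camera adjusted p = 2.87e-10; adjusted p = 0.333 with an estimated correlation). The giant muscle kinase gene bt changed by 10.43 (SE 0.46) and Act87E by 6.76 (SE 0.33). Haemocyte and fat body markers rose in 21 of 24 cases with 0 falls both ways. Their median was 5.81, or 5.36 with 2 at their bound (camera adjusted p = 1.28e-07; adjusted p = 0.333 with an estimated correlation). Without control replicate 2 it was 8.73. NimC1 was at least 1063-fold higher, Hml changed by 11.58 (SE 0.49), the larval serum protein gene Lsp1beta by 11.31 (SE 0.74), and eater had a count ratio of 2247 (622 to 18557). Neuronal genes rose in 13 of 16 cases with 0 falls both ways. Their median was 5.56, or 4.78 with 3 at their bound (camera adjusted p = 9.94e-05; adjusted p = 0.333 with an estimated correlation). The value of cpx was 9.44 (SE 0.58). Niche, escort and early follicle cell markers rose in 21 of 27 cases and fell in 3 both ways. The list's median stood at 4.16, or 4.04 with 3 at their bound (camera adjusted p = 9.94e-05; adjusted p = 0.267 with an estimated correlation). The value of ci was 6.67 (SE 0.32). Follicle cell and border cell markers had a median of 2.04 (12 of 18 higher and 2 lower both ways, camera adjusted p = 0.00762; adjusted p = 0.333 with an estimated correlation). The length correction left 0.81, with 8 higher and 4 lower. BMP signalling genes had one of 1.52 (13 of 20 higher and 1 lower both ways, camera adjusted p = 0.00518; adjusted p = 0.333 with an estimated correlation). Over the 19 of them with a transcript length the median was 1.85 before the length correction and 0.98 after it. Fas2 changed by 5.83 (SE 0.29) and the collagen gene vkg by 4.03 (SE 0.32). Heat shock protein genes went the other way from nosGAL4, with 11 of 18 lower and 3 higher both ways. Their median was −1.68 (camera adjusted p = 0.0227; adjusted p = 0.525 with an estimated correlation). Hsp26 changed by −5.07 (SE 0.31), Hsp27 by −3.70 (SE 0.25) and stv by 3.25 (SE 0.35). The heat shock call was lost without control replicate 2 (−1.14, adjusted p = 0.0825) and without nosGAL4 knockdown replicate 1 (−1.58, adjusted p = 0.0534) or replicate 2 (−1.58, adjusted p = 0.053). Ribosomal protein genes were lower in 51 of 79 cases and higher in 1 both ways. Their median was −0.85 (camera adjusted p = 1.51e-06; adjusted p = 0.525 with an estimated correlation). RpL41 changed by −1.90 (SE 0.31). After the length correction the median was −0.37, with 27 lower and 2 higher. Not called were the yolk list (median 0.78, 4 of 9 higher and 1 lower both ways, camera adjusted p = 0.231), the oviduct, spermatheca and gut list (0.51, 3 of 12 higher and 1 lower both ways, camera adjusted p = 0.542) and the testis-enriched list (−0.74, 3 of 8 lower and 1 higher both ways, camera adjusted p = 0.542). The ecdysone list (0.89, 9 of 22 higher and 5 lower both ways, camera adjusted p = 0.295), the apoptosis and stress list (1.06, or 0.71 with 1 at its bound, 12 of 28 higher and 10 lower, 13 and 10 adjusted over the list alone, camera adjusted p = 0.514) and the early oogenesis list (−0.02, 7 of 14 lower and 5 higher both ways, camera adjusted p = 0.542) were not called either. In these lists Xrp1 changed by 4.48 (SE 0.26), the ecdysone-induced Blimp-1 by 7.95 (SE 0.50) and the germline ribosomal protein gene RpS5b by −5.20 (SE 0.53).

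**Figure D2:**
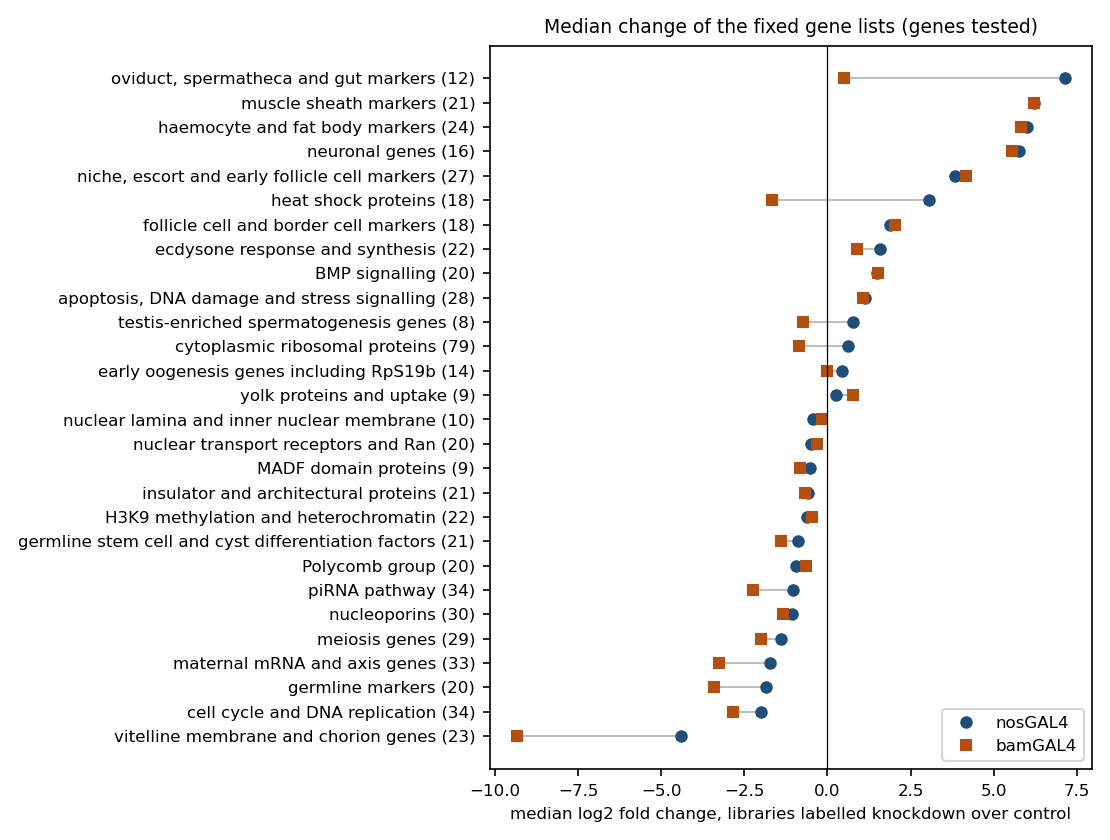
Median log2 fold change of each of the 28 lists, libraries labelled knockdown over control, with nosGAL4 (circles) and bamGAL4 (squares), and the number of genes tested in brackets; lines join the values of 1 list. Muscle sheath markers lie at 6.23 and 6.21, vitelline membrane and chorion genes at −4.40 and −9.34, and heat shock protein genes at 3.06 and −1.68.

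In all, 3138 genes were higher and 2961 lower with bamGAL4 in the libraries labelled knockdown (68.1% of 8957), of which 2788 and 2409 changed at least 2-fold. With scaling to ribosomal protein genes the numbers were 4123 higher and 1200 lower. They were 2841 and 3385 with library totals and 2776 and 3197 with the length correction, so this balance too depended on the scaling. Groups did not overlap for 87.2% of genes, against 33.3% by chance. Other large rises were those of stan, a planar polarity cadherin (at least 384-fold), Rgk1 (at least 149-fold), CG45263 (at least 538-fold), CG9400 (at least 406-fold) and the calcium sensor gene Frq2, with a count ratio of 4879 (875 to 192740). The piRNA helicase gene armi was at least 290-fold higher, but its value is uncertain, since it was at 0 CPM in 6 libraries and lies within a gene on the same strand. The largest other falls were those of CG31262 (at least 319-fold lower) and CG43965 (at least 263-fold). The histone gene His1:CG33858 was at least 121-fold lower, and lost its call with no filter on low counts (edgeR test, adjusted p = 0.0808). It is 1 of many near-identical copies, and its call was lost without bamGAL4 knockdown replicate 1 (adjusted p = 0.0817) or 2 (adjusted p = 0.0777) and without nosGAL4 control replicate 1 (adjusted p = 0.052) or 2 (adjusted p = 0.0544).

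Most genes had the same sign of change with both drivers. The muscle sheath medians, 6.23 and 6.21 with the TMM scaling, were 5.71 with nosGAL4 and 7.07 with bamGAL4 with ribosomal protein scaling. Of the genes higher with nosGAL4, 2500 were higher with bamGAL4 too, where independent lists would share 1052.4, and 1905 of those lower were also lower, against 761.32. Opposite calls were made for 45 genes higher and 15 genes lower with nosGAL4. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.824 and Spearman rho = 0.845, and 83.8% had the same sign. No control library served both drivers.

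**Figure D3:**
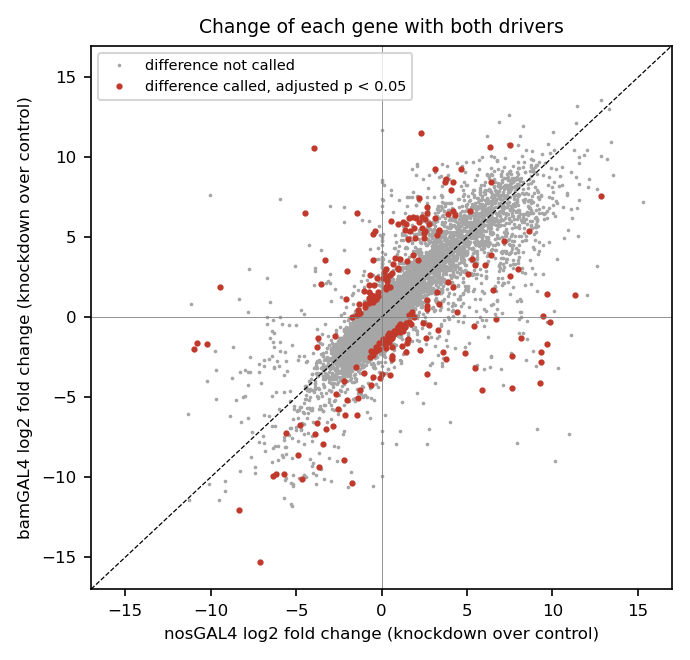
Log2 fold change of each of the 8957 genes, libraries labelled knockdown over control, with nosGAL4 (horizontal) and bamGAL4 (vertical); red points are the 240 genes whose change differed between drivers and the dashed line marks equal change. The sign of change is the same with both drivers for 83.8% of the genes.

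The change of heat shock genes differed between drivers by camera, which asks whether the members of a list moved more than other genes, and by fry, which asks whether they moved. The ribosomal protein, eggshell and early oogenesis lists passed by camera and not by fry. The difference, nosGAL4 change minus bamGAL4 change, had a median of 3.88 for heat shock protein genes (9 of 18 called, all positive, and 16 adjusted over the list alone; camera adjusted p = 1.52e-12; fry adjusted p = 0.036; adjusted p = 0.708 with an estimated correlation), or 2.46 with ribosomal protein scaling. Hsp22 rose by 2.63 with nosGAL4 and changed by −3.55 with bamGAL4 (difference 6.18, SE 0.48, adjusted p = 0.000364), but its values are uncertain, since it overlaps CG4456, another member of the list, on its own strand. Hsp70Aa, chosen after its values were seen and 1 of several near-identical copies, was at 214 and 69 CPM in the nosGAL4 controls, 1570 and 1880 CPM in the nosGAL4 libraries labelled knockdown, 1120 and 2630 CPM in the bamGAL4 controls and 523 and 298 CPM in the bamGAL4 libraries labelled knockdown. Ribosomal protein genes had a median difference of 1.47 (25 of 79 called, all positive, and 77 adjusted over the list alone; camera adjusted p = 6.05e-25; fry adjusted p = 0.0987; adjusted p = 0.708 with an estimated correlation). The length correction left 0.73, with 2 called. The median of bamGAL4 minus nosGAL4 was 0.97 in the controls (79 of 79 above 0, 36 called). In the libraries labelled knockdown it was −0.51 (2 called). A large part of the ribosomal protein difference thus lay between the controls, labelled WT. RpL41 had a difference of 2.18 and RpL29 of 1.90, and both lost their call without at least 1 library. Vitelline membrane and chorion genes had a median difference of 5.20, with 5 of 23 called positive (17 positive and 1 negative adjusted over the list alone; camera adjusted p = 1.03e-07; fry adjusted p = 0.17; adjusted p = 0.708 with an estimated correlation), or 2.54 without nosGAL4 knockdown replicate 1. Early oogenesis genes had one of 1.56 (2 of 14 called positive, 4 adjusted over the list alone; camera adjusted p = 0.00277; fry adjusted p = 0.15; adjusted p = 0.708 with an estimated correlation). That median was 0.07 with ribosomal protein scaling, and 1.24 with 0 members called after the length correction.

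**Figure D4:**
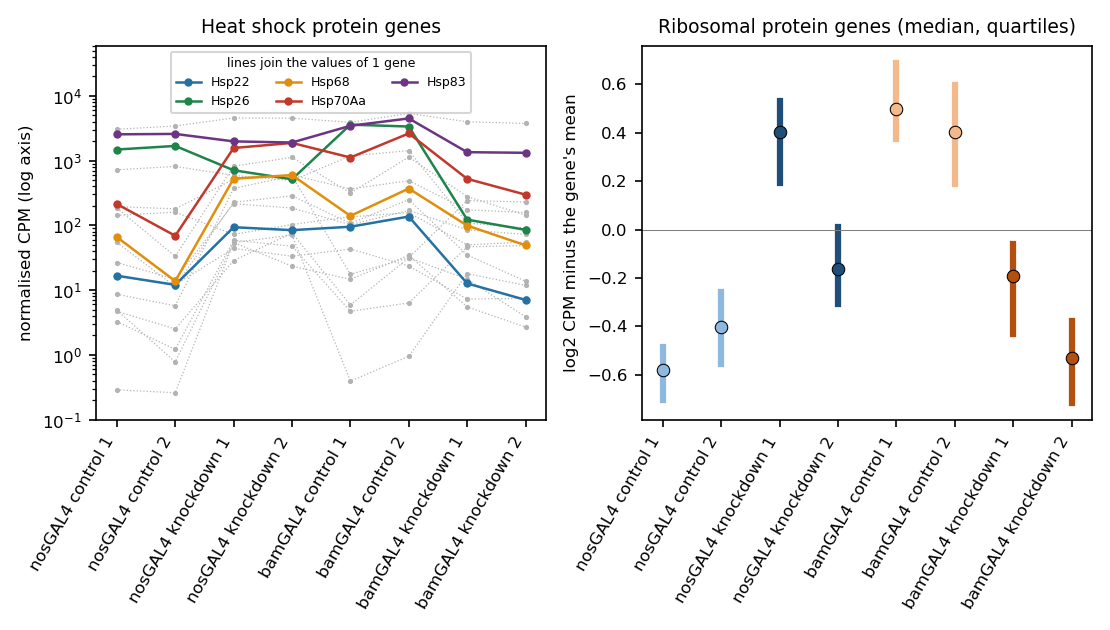
Left, normalised CPM (log axis) of the heat shock protein genes in each library, with 5 genes in colour and lines joining the values of 1 gene; right, median (points) and quartiles (bars) over 79 ribosomal protein genes of log2 CPM minus the gene's mean over the libraries. Hsp70Aa runs from 69 to 2630 CPM, and the ribosomal protein medians run from −0.58 in a nosGAL4 control to 0.50 in a bamGAL4 control.

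The oviduct, spermatheca and gut list was not called for the difference (median 5.58, 2 of 12 positive and 2 negative, 6 and 3 adjusted over the list alone; camera adjusted p = 0.325, fry adjusted p = 0.384). The protease gene Jon99Ciii was at 0 and 0.0866 CPM in the nosGAL4 controls and at 76.5 and 17.5 CPM in the libraries labelled knockdown, and with bamGAL4 at 12.6 and 23.3 CPM against 5.05 and 6.36 CPM (difference 11.32, SE 1.35, adjusted p = 0.00898). The amylase gene Amy-p (9.48, SE 1.10), the proteases Jon99Ci (12.14, SE 1.76) and yip7 (10.43, SE 1.96) and the lysozyme gene LysD (11.51, SE 2.13) also had positive differences. Their rise with nosGAL4 lay mostly in knockdown replicate 1. Values in replicates 1 and 2 were 70.1 and 15.7 CPM for Amy-p and 14.6 and 1.99 CPM for Jon99Ci. They were 11.4 and 0.796 CPM for yip7 and 15.0 and 1.46 CPM for LysD. FASN3 was at 4.6 and 1.73 CPM in the nosGAL4 controls, 37.0 and 17.9 CPM in the libraries labelled knockdown, and with bamGAL4 at 1.05 and 0.238 CPM against 352 and 361 CPM (difference −6.15, SE 0.88), and FASN2 had a difference of −5.26 (SE 0.74). The sodium channel auxiliary gene tipE (−6.90, SE 1.01), mei-217 (−11.37, SE 1.97) and kappaB-Ras (−8.55, SE 1.54) also had negative differences, and tipE overlaps CG18675 on its own strand, so its values are uncertain too. Fitted values of genes with groups at 0 counts are no bounds. With no filter on low counts LysD (edgeR test, adjusted p = 0.0746) and yip7 (adjusted p = 0.0901) lost their calls. In total the difference passed for 240 of 8957 genes, 136 positive and 104 negative. The split was 119 and 161 with RLE size factors, 104 and 176 with library totals alone and 94 and 3339 with scaling to ribosomal protein genes. The number of genes rested on single libraries. It was 77 and 55 without nosGAL4 control replicates 1 and 2, 463 and 1570 without nosGAL4 knockdown replicates 1 and 2, 86 and 179 without bamGAL4 control replicates 1 and 2, and 34 and 29 without bamGAL4 knockdown replicates 1 and 2. Each of the 10 named genes lost its call without at least 1 library, and LysD (adjusted p = 0.0592), yip7 (0.0603) and FASN2 (0.0502) lost it with the length correction. Without bamGAL4 knockdown replicate 1 the adjusted p was 0.0989 for Jon99Ci, 0.188 for LysD, 0.0758 for Jon99Ciii, 0.182 for yip7, 0.108 for mei-217, 0.114 for kappaB-Ras and 0.0758 for FASN3. Replicate 2 of that group, left out, gave 0.0842 for Jon99Ci, 0.211 for LysD, 0.0582 for Jon99Ciii, 0.203 for yip7, 0.0782 for mei-217, 0.0582 for tipE and 0.0668 for FASN3. Omitting bamGAL4 control replicate 1 gave 0.0657 for Jon99Ci, 0.0839 for LysD, 0.07 for yip7, 0.0827 for mei-217 and 0.0744 for kappaB-Ras, and omitting replicate 2 gave 0.0643 for LysD, 0.0596 for yip7, 0.0534 for mei-217 and 0.0501 for kappaB-Ras, FASN3 and FASN2. Without nosGAL4 control replicate 1 it was 0.0538 for Jon99Ci, 0.166 for LysD, 0.0552 for Jon99Ciii and mei-217, 0.201 for yip7 and 0.0617 for kappaB-Ras. Without nosGAL4 control replicate 2 it was 0.0659 for Jon99Ci, 0.143 for LysD, 0.06 for Jon99Ciii, 0.151 for yip7, 0.0539 for Amy-p and 0.0856 for kappaB-Ras.

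Smaller list differences passed by camera and not by fry. These were the differences of germline markers (0.70, 2 of 20 positive, 3 adjusted over the list alone; camera adjusted p = 0.0263, fry 0.32), meiosis genes (0.71, 1 of 29 positive and 1 negative, 5 and 1 adjusted over the list alone; camera 0.0245, fry 0.281), the Polycomb group (−0.48, 0 of 20, 1 negative adjusted over the list alone; camera 0.0245, fry 0.0987) and haemocyte and fat body markers (−0.24, 1 of 24 negative, 3 adjusted over the list alone; camera 0.0425, fry 0.291). Each had an adjusted p = 0.708 with an estimated correlation. The germline marker call was lost without nosGAL4 control replicate 2 (0.81, adjusted p = 0.0929), nosGAL4 knockdown replicate 1 (0.08, adjusted p = 0.401), bamGAL4 control replicate 1 (0.61, adjusted p = 0.102) or bamGAL4 knockdown replicate 1 (0.48, adjusted p = 0.256), and its median was 1.17 without nosGAL4 knockdown replicate 2. The meiosis call was lost without nosGAL4 control replicate 1 (0.60, adjusted p = 0.0527), nosGAL4 knockdown replicate 1 (0.20, adjusted p = 0.267) or bamGAL4 knockdown replicate 1 (0.66, adjusted p = 0.105), and the Polycomb call without nosGAL4 control replicate 1 (−0.44, adjusted p = 0.0521). The Polycomb median was −0.09 after the length correction and −1.95 with ribosomal protein scaling. The haemocyte and fat body call was lost without nosGAL4 control replicate 1 (−0.09, adjusted p = 0.17), nosGAL4 knockdown replicate 1 (−0.50, adjusted p = 0.118), bamGAL4 control replicate 1 (−0.15, adjusted p = 0.35) or bamGAL4 knockdown replicate 1 (−0.15, adjusted p = 0.105), and its median was −0.76 without nosGAL4 control replicate 2, −0.40 without nosGAL4 knockdown replicate 2 and −1.08 without bamGAL4 control replicate 2. The call was lost as well with RLE size factors (−0.37, adjusted p = 0.0642), library totals (−0.38, adjusted p = 0.119), ribosomal protein scaling (−1.43, adjusted p = 0.69) and the replicate block (−0.20, adjusted p = 0.0784). With scaling to ribosomal protein genes alone the germline marker and meiosis medians turned to −0.81 and −0.79. Nucleoporins showed no called difference (median 0.33, 0 of 30 genes both ways, camera adjusted p = 0.633, with 0 by the edgeR test).

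Within each driver fry called every list that camera called, and further ones. With nosGAL4 these were the early oogenesis (fry adjusted p = 0.0338), ecdysone (0.000539) and apoptosis and stress lists (0.000545). With bamGAL4 they were the transport (0.00915), H3K9 (0.0134), insulator (0.00529), MADF (0.0134), yolk (0.0115), oviduct, spermatheca and gut (0.0119), ecdysone (0.00119) and apoptosis and stress lists (0.00488). The ecdysone median with bamGAL4 was −0.05 after the length correction.

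Scaling moved the whole distribution as well. Relative to the TMM scaling, the median log2 fold change of all genes shifted by −0.38 with library totals and −0.52 with ribosomal protein scaling for nosGAL4, and by 0.22 with RLE size factors, −0.22 with library totals and 0.85 with ribosomal protein scaling for bamGAL4. For the difference the shifts were −0.15, −0.20 and −1.39, and the transcript length correction shifted the medians by −0.22, −0.13 and −0.12. With bamGAL4 and ribosomal protein scaling the medians were −0.50 for nucleoporins, −1.12 for meiosis genes, −1.39 for the piRNA pathway, −0.54 for germline stem cell and cyst factors, −0.85 for heat shock genes and 2.40 for BMP signalling, and each of these lists was still called.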

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

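The tests chosen only after the result was seen were those of swapped labels, of a larger somatic share, of a batch shared by both groups of a driver, of stress differing between the 4 groups, of a lower germline share for the nucleoporins, and the transcript length correction. The tests of length-matched and expression-matched lists were chosen before their results were seen.

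No fall of the mRNA of stwl was detected in the libraries labelled knockdown with either driver. Swapped labels are argued against, since the germline markers were lower in those libraries with both drivers, with an upper quartile of their log2 changes at −0.604 for nosGAL4 and −2.17 for bamGAL4. A larger share of somatic RNA may hide a loss of stwl in germ cells, but its test cannot decide this. The log2 change of stwl minus the follicle and border cell marker median was −0.735 with nosGAL4 and −1.61 with bamGAL4, as that explanation needs. The median change of all genes, 0.105 and −0.0569, also lay below the follicle marker medians of 1.89 and 2.04. A gene that was not depleted could thus pass this test as well. The medians of lists of somatic cells were unequal with nosGAL4, at 1.89 for follicle markers, 6.23 for muscle markers and 7.14 for oviduct, spermatheca and gut markers. The last of these was partly set by the expression filter, and was 5.24 with 7 members at their bound. Unequal rises alone do not decide whether the somatic share changed uniformly, since the expression of each list in germ cells is not known here. The vitelline membrane and chorion genes that follicle cells make had a median of −4.40. A uniform rise of the somatic share does not account for that fall, and a change among the somatic tissues stays open. Reads from the hairpin stay open as well, and the counts do not show whether stwl was depleted in germ cells.

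Heat shock and ribosomal protein genes differed between drivers by a camera test of the difference itself, with medians of 3.88 and 1.47 (0.05 when scaled to the ribosomal protein genes themselves; fry adjusted p = 0.036 and 0.0987; adjusted p = 0.708 for each with an estimated correlation). Across genes the difference followed transcript length (Spearman rho −0.462, from a median of 0.871 for transcripts up to 996 bases to −0.685 from 3787 bases), but both lists lay at percentile 100 of 10000 length-matched lists, whose median was 0.231 for heat shock genes and 0.814 for ribosomal protein genes. The length correction left 3.22 for heat shock genes, with 9 called before and 9 after. It left 0.732 for ribosomal protein genes, of which 2 rather than 25 were called. Length may thus account for part of the ribosomal protein difference, and whether for the whole stays open. The matched lists hold genes drawn independently, while the estimated correlation was 0.716 among ribosomal protein genes and 0.407 among heat shock genes. A batch shift shared by both groups of a driver cancels in the difference, so the test of it could not decide anything about this pattern. For heat shock genes the median of bamGAL4 minus nosGAL4 was 2.09 in the controls and −2.14 in the libraries labelled knockdown. For ribosomal protein genes it was 0.97 in the controls (36 of 79 called) and −0.51 in the libraries labelled knockdown (2 called). A batch particular to 1 group was not tested. Stress that differed between the 4 groups at growth or dissection cannot be told apart from an effect of the knockdown, since each group was its own condition and 0 of the 18 heat shock genes went against the pattern. The controls, labelled WT, already differed from each other, with 17 of the 18 heat shock genes above 0 and 6 called. The stage at which each driver targets stwl cannot account for that part. It stays open as a biological explanation for the part between the libraries labelled knockdown.

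Of the 30 nucleoporin genes 20 fell and 0 rose with nosGAL4, and 21 fell and 3 rose with bamGAL4. After the length correction 26 fell with nosGAL4 and 29 with bamGAL4, with 0 rises in each. That correction also takes out real changes that follow length. Transcripts from 3787 bases had median changes of 0.66 with nosGAL4 and 1.36 with bamGAL4 before it. The larger counts are therefore no separate support for the fall. The lower nucleoporin values bear on the nuclear pore question in the study's title. A lower share of germline RNA may account for it, but its test cannot decide this. The nucleoporin median lay above the germline marker median, by 0.78 with nosGAL4 and 2.06 with bamGAL4, as a list that somatic cells also express would. The Polycomb medians, −0.94 and −0.64, also lay between the germline marker medians, −1.86 and −3.41, and 0. So did the medians of expression-matched random lists, −0.170 and −0.209. The fall of the nucleoporins went beyond that of genes of similar expression, with the median at percentile 0 of 10000 expression-matched lists with either driver (random medians −0.170 and −0.209), so it was not a shift of all genes. The matched genes were drawn independently and without regard to germline expression, while the nucleoporins had an estimated correlation of 0.34. The percentile therefore does not set nucleoporins apart from other genes expressed in germ cells. The list was called with both drivers under each scaling tried, but not with an estimated correlation (adjusted p = 0.413 with nosGAL4 and adjusted p = 0.525 with bamGAL4). A fall within germ cells and a fall in the number of germ cells cannot be separated by whole-ovary counts.

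The other differences between drivers, each passing a test of the difference itself (camera for lists), are given as nosGAL4 change minus bamGAL4 change. In all 240 genes differed, or from 29 to 1570 on leaving out 1 library, and of the 171 named genes tested 34 did. Of these 34, 7 kept their call without each library in turn (Cp36, Hsp22, Hsp23, Hsp26, Hsp27, mtrm and Oamb) and 27 lost it without at least 1. Besides the lists above, 6 lists differed by camera and none of them by fry (adjusted p from 0.0987 to 0.32) or with an estimated correlation (adjusted p = 0.708 for each): the Polycomb group (−0.481, or −0.09 after the length correction), germline markers (0.704), early oogenesis genes (1.56), meiosis genes (0.714), vitelline membrane and chorion genes (5.20) and haemocyte and fat body markers (−0.24). Heat shock genes that differed were Hsp22 (6.18), Hsp23 (4.07), Hsp26 (3.69), Hsp27 (3.20) and stv (2.80). Ribosomal protein genes that differed were RpL22 (1.46), RpL28 (1.80), RpL29 (1.90), RpL31 (1.89), RpL36A (1.95), RpL41 (2.18) and the germline paralog RpS5b (3.15). Egg, yolk and germline genes that differed were Cp36 (5.48), Femcoat (3.74), yellow-g2 (8.15), bcd (8.64), exu (1.60), mtrm (4.11), otu (1.96) and the yolk receptor gene yl (3.42), each with the deeper fall in bamGAL4. Digestive genes that differed were Amy-p (9.48), Jon99Ci (12.14), Jon99Ciii (11.32), LysD (11.51) and yip7 (10.43), whose rise with nosGAL4 lay mostly in knockdown replicate 1. The peptidase gene Ance-5 differed by 5.28. Negative differences were those of the lipoprotein gene apolpp (−4.63), the fatty acid synthases FASN2 (−5.26) and FASN3 (−6.15), the octopamine receptors Oamb (−2.98) and Octbeta2R (−2.61), tipE (−6.90), mei-217 (−11.37) and kappaB-Ras (−8.55).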

How the results depend on the processing

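Directions were stable for most named genes, while the number of genes that differed between drivers and the stwl value were not. The transcript length correction was chosen after seeing the data. With DESeq2 249 of 250 gene results kept their direction and side of the threshold, with library totals 250 of 250, with the replicate block 249 of 250 and with ribosomal protein scaling 244 of 250. Leaving out 1 library kept between 240 and 249. With an estimated correlation 45 of the 84 list results, all those called, were no longer called. Correlation between genes does not account for every such loss. The niche, escort and early follicle cell list had an estimated correlation of −0.00911, below the preset 0.01. Its camera adjusted p still went from 4.54e-05 to 0.226 with nosGAL4 and from 9.94e-05 to 0.267 with bamGAL4. With fry 7 list results, all of the difference, were no longer called and 11 others were newly called. A group left with 1 library is assumed to vary like the others. In simulated data 15.91% of genes changed 2-fold were recovered for nosGAL4 and 2.273% for the difference, so most of the 2-fold changes put in were missed. The cause was not tested for the values below, except that leaving out chromosome 3 tests fewer genes.

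Outside chromosome 3 there were 1677 higher and 1304 lower genes with nosGAL4, 1799 and 1671 with bamGAL4, and 115 that differed between drivers. Ribosomal protein scaling gave 1200 genes lower with bamGAL4 and 3433 that differed. DESeq2 gave 1064 that differed, no filter 537, the length correction 132, and leaving out 1 library from 29 to 1570. The log2 fold change of stwl with nosGAL4 no longer passed at 0.7231 with library totals, 0.4972 with ribosomal protein scaling, 1.066 in the driver's own 4 libraries, 0.8244 with the length correction, and ran from 0.4622 to 1.594 on leaving out 1 library. With bamGAL4 it was 1.304 with ribosomal protein scaling, where it passed, and −0.3241 with the length correction. The correlation of both drivers' effects was 0.691 with no filter, 0.862 with the strict filter, 0.885 from each driver's own 4 libraries and from 0.74 to 0.796 on leaving out 1 library. Su(var)2-HP2 turned to −0.04977 with bamGAL4 after the length correction. With the replicate block, 2761 genes were higher and 2142 lower with nosGAL4, 2991 and 2752 with bamGAL4, and 169 differed. Libraries of the same number did not deviate together (correlations −0.0375 and −0.00325), so no pairing by number was detected. With 2 libraries per group this does not exclude a weak one.

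The direction of the list test turned for lists that were not called in the main fit, whose medians were then as follows. The testis-enriched list with nosGAL4 was at 0.9037 with the replicate block, and the oviduct, spermatheca and gut list with bamGAL4 at 1.402 with ribosomal protein scaling. For the difference with ribosomal protein scaling, nucleoporins were at −1.069, the lamina list at −1.521, niche markers at −1.447 and neuronal genes at −1.349, where the neuronal list passed (adjusted p = 0.0308). That setting also newly called the differences of the maternal mRNA list (−0.8449, adjusted p = 0.0186) and of the oviduct, spermatheca and gut list (4.283, adjusted p = 5.49e-08). With RLE size factors and library totals the lamina list was at −0.3074 and −0.3575 and neuronal genes at −0.1521 and −0.2087. The replicate block gave −0.1149 for the transport list and −0.1726 for the lamina list, and fry −0.1021 for the transport list and −0.02716 for neuronal genes. On leaving out 1 library the yolk list with nosGAL4 ran from 0.05751 to 0.7588 and the oviduct, spermatheca and gut list with bamGAL4 from −1.176 to 4.374. The differences ran from 0.1263 to 0.4419 for nucleoporins, −0.1915 to 0.02752 for transport, −0.2478 to −0.001127 for the lamina, −0.3275 to 0.02218 for H3K9, −0.308 to 0.08348 for insulators, −1.28 to 0.5317 for neuronal genes and 0.06219 to 1.03 for the cell cycle.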

Other observations

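The genes and the digestive enzyme list described here were chosen after their values were seen, while the test of chromosome 3 was chosen before its result was seen. Homeotic genes, which pattern the trunk segments and were near the detection floor in most control libraries, were higher in the libraries labelled knockdown. Of the 8 Hox genes 4 were tested, and these 4 were higher with both drivers. Their control values were 1.06 CPM or less, so the expression filter kept them largely through the libraries where they were high. The count of 4 of 4 was thus largely set by the filter. In the same libraries the muscle sheath, haemocyte and fat body, and neuronal markers had medians of 6.23, 6.02 and 5.76 with nosGAL4 and 6.21, 5.81 and 5.56 with bamGAL4. The neuronal medians too were partly set by the filter. The abdominal gene abd-A (3R:16807214-16830049) went from 1.06 and 0.952 CPM to 348 and 576 CPM with nosGAL4 and from 0.262 and 0.554 CPM to 569 and 644 CPM with bamGAL4 (log2 fold changes 8.83, SE 0.40, and 10.39, SE 0.44). With nosGAL4 Antp changed by 6.43 (SE 0.45), and with bamGAL4 its count ratio was 1388 (95% counting interval 248.72 to 54858). The count ratio of Abd-B was 203.71 (55.863 to 1690.5) with nosGAL4 and 684.48 (122.46 to 27073) with bamGAL4. The last of them was Ubx, which changed by 3.17 (SE 0.96) with nosGAL4 and went from 0 CPM to 7.09 and 7.95 CPM, at least 50.6-fold higher, with bamGAL4.

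Genes of muscle and fat body rose in the libraries labelled knockdown. The muscle myosin gene Mhc was at 41.5 and 44.5 CPM in the nosGAL4 controls against 4460 and 6280 CPM, and at 36.8 and 60.9 CPM in the bamGAL4 controls against 10300 and 9250 CPM. The larval serum protein gene Lsp2 went from 2.69 and 8.92 CPM to 537 and 157 CPM with nosGAL4 and from 0.524 and 2.06 CPM to 1780 and 1230 CPM with bamGAL4. The summed CPM of 23 digestive enzyme genes was at most 119 in the nosGAL4 controls, 563 and 162 in the nosGAL4 libraries labelled knockdown, 423 and 650 in the bamGAL4 controls and 240 and 264 in the bamGAL4 libraries labelled knockdown. The gene armi was at 0 CPM in 6 libraries and at 34.9 and 51.8 CPM in the bamGAL4 libraries labelled knockdown, while CG46463, which overlaps it on the same strand, was at 78.3 CPM or more in every library.

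Balancer chromosomes differed between the genotypes, which could change genes on chromosome 3 apart from any effect of stwl. If so, more of the genes there would have been called. With nosGAL4 58.9% of the 3880 genes tested on chromosome 3 were called, against 59.4% of the 5039 elsewhere, a difference of −0.531 percentage points (two-sided Fisher's exact test, p = 0.617). The corresponding shares with bamGAL4 were 67% and 68.9%, a difference of −1.89 points (Fisher's exact test, p = 0.0603). The balancers are therefore unlikely to account for the number of genes called, although effects on single genes of chromosome 3 were not excluded.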
